A study of Mus musculus with 9 samples.

How the data were processed

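Gene expression was measured on 9 Affymetrix arrays, 1 per mouse, in motor neurons cut by laser from the lumbar spinal cord. Per the labels' protocols, the animals had surgery at postnatal day 1 and were killed at day 13, the cords were fixed by perfusion with paraformaldehyde and frozen, and sections of 16 µm were used for microdissection. About 100 cells were collected per cap, the cells on an array came from 1 animal, and RNA was isolated with a column kit including a DNase step. The labelled cRNA was made by 2 rounds of amplification for small samples, per the labels' protocols.

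The deposited values are MAS5 signals, a linear intensity per probe set in arbitrary units, per the submitters' processing notes and the values themselves. MAS5 sets each probe against its mismatch partner and scales every array to one target. In these data the mean after trimming 2% of the probe sets at each end was 100 on every array, so the authors' scaling was kept. The MAS5 version and any detection filter are not given in the sources used here. Detection calls were not used here, and a probe set's brightness was judged by its signal alone. Double amplification favours the 3' end of transcripts, and differences in capture can bring RNA of neighbouring cells onto an array. The array number limits the precision, with 3 arrays per group.

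The array holds 22690 probe sets, of which 64 controls were left out. Of the remaining 22626, 20380 named 1 gene symbol in the platform annotation used, 691 named several and 1555 were not listed there. Platform annotation can be old; 20351 symbols were looked up through their gene ID and 0 changed. No gene was named from a probe set with several symbols. All 9 value columns belonged to the 9 samples, and 0 pairs of columns were identical.

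Each signal had 16 added and was taken to log2. A fold change on this log2(signal + 16) scale understates the change of dim genes. The brighter 50% of probe sets by the mean over all 9 arrays was tested, which was 11313 probe sets and 7254 named genes, with a lowest mean log2(signal + 16) of 5.63. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on mean signal) in 1 model with a mean per group. The model had 6 residual degrees of freedom and a prior of 4.93. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p of 0.05. The 3 comparisons were SMA minus wild type, transplanted SMA minus SMA, and transplanted SMA minus wild type.

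Gene lists were 29 sets of pathway genes, complexes and cell type markers. A gene entered by its brightest probe set that named this gene alone, and a list needed 5 tested members. Of these lists, 27 were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The estimated correlation had a median of 0.14 over these lists (-0.028 to 0.69). The p-values at the preset are therefore too small for lists whose genes move together. Camera compares a list with the other genes; fry asks whether a list's genes move, on balance, one way. The list of sex-linked transcripts was read as values per array, and the erythroid and plasma list had 4 tested members and no list test. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone.

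The tests, groups, lists, naming rule and main alternatives were fixed before the data were examined. Genes named per comparison were those past the threshold whose groups did not overlap, up to 8 per direction by size, filled up to 5 with the smallest unadjusted p where fewer passed. To these came the 3 tested members with the smallest p of each list past its test and up to 2 members of other lists where the unadjusted p was under 0.05. A fixed set was Smn1, Chat, Slc18a3, Slc5a7, Prph, Isl1, Nefl, Nefm, Nefh, Hspa5, Cdkn1a, Gfap and Mbp. Chat has no value here, because no probe set named it alone in the annotation used. Genes past the test in both SMA minus wild type and transplanted SMA minus SMA would also have been named, and there were 0. Genes named outside this rule are marked as chosen after their values were seen.

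The alternatives were quantile normalisation, centring on array medians, pseudocounts of 1 and 64, no filter and a stricter filter on dim probe sets, eBayes without trend or robust, array weights, and a fit of the 6 arrays compared. Further ones were the sample number as a block, leaving out probe sets with shared probes, leaving out each array in turn, an added minimum log2 difference of 1, and a threshold of 0.10. For gene lists, the mean of all probe sets of a gene was also tried. Covariates for hybridisation controls, Xist and muscle transcripts, and fits without the 3 arrays numbered 3 or without SMA 1 and SMA 2, were chosen after seeing the data. The covariance of comparisons that share arrays was set beside 1000 simulations of unchanged groups with the same residual spread.

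The limma step was tested on simulated data for SMA minus wild type, with 11313 probe sets, 5 simulations and 100 probe sets changed per size. It recovered 52% of those changed by a log2 of 1 and 92.6% of those changed by 2, and 4.99% of the calls were false. The simulated noise was independent between probe sets. These rates therefore need not hold for the real arrays, where many probe sets can move together.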

Results

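Spinal muscular atrophy (SMA) is a loss of motor neurons caused by too little of the SMN protein, which assembles the small nuclear ribonucleoproteins of the spliceosome. The samples were laser-cut motor neurons from the lumbar cord of 13-day-old mice in 3 groups of 3 animals. These were wild type given vehicle, transgenic SMA given vehicle, and SMA transplanted at postnatal day 1 with cells, which the labels do not name and which are neural stem cells from what is known of the study. Each array held the neurons of 1 animal. MAS5 signals had medians of 31.4 to 35.8 per array and total signals of 3226815 to 3453157, and the 50 brightest probe sets took 7.95% to 10.3% of the total. Correlations of log2 signals were 0.904 to 0.975 between arrays of one group (median 0.945, 9 pairs) and 0.91 to 0.962 between groups (median 0.942, 27 pairs). The hybridisation controls read 267 on wild type 3 and 297 on SMA 3, against 168 to 229 on the other arrays. The same 2 arrays had the highest 18S ribosomal RNA (2889 and 2748 against 819.6 to 1819) and the highest 3'/5' ratios of actin (3.66 and 4.32 against 2.48 to 3.11), while the Gapdh ratio was highest on SMA 1 (4.26).

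Smn1, the gene lost in SMA, was too dim to test. Its signals were 5.1, 3.7 and 1.8 in wild type, 4, 1.3 and 3.1 in SMA, and 2, 1.8 and 4.2 in transplanted SMA, at percentile 5.75 of all probe sets by mean signal. At this level the probe set checks none of the labels, and which transcript of the transgenic animals it would read is not given in the sources used here.

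The arrays read both neuronal and glial transcripts; signals of different probe sets are not comparable amounts, so they do not settle how pure the captures were. Nefl, the light neurofilament chain, had a mean signal of 871 ± 272 (SD, n = 9) and Stmn2, a microtubule regulator of growing axons, 452 ± 215. Markers that set motor neurons apart had means of 13.4 ± 11.9 for the vesicular acetylcholine transporter Slc18a3, 7.9 ± 3.03 for the choline transporter Slc5a7, 26.9 ± 24.6 for the intermediate filament Prph and 8.83 ± 3.82 for the transcription factor Isl1. They lay at percentiles 26.7, 18.6, 40.1 and 20.5 of all probe sets by mean signal, all too dim to test. Their signals do not show that motor neurons were enriched in the captures. Of 32 motor neuron genes with a probe set, 12 were bright enough to test, Isl2 among them at 59.5 ± 28.2. Of the myelin transcripts, Mbp had a mean of 10700 ± 1620 and Mobp 6190 ± 2380. The water channel Aqp4 of astrocytes reached 1410 ± 502, the collagen gene Col1a2 1310 ± 973 and the complement gene C1qa of microglia 423 ± 199. Apart from Nefl, Slc18a3, Slc5a7, Prph, Isl1, Isl2 and Mbp, these genes were chosen after their values were seen.

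**Figure D1:**
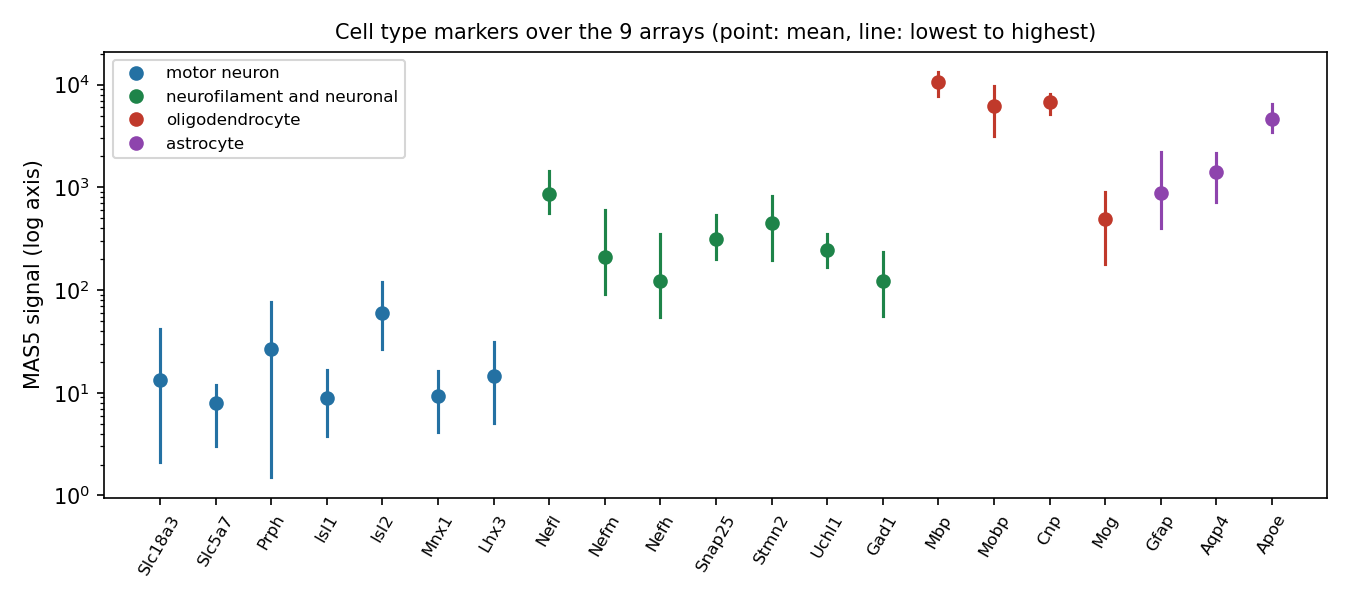
Mean MAS5 signal (log axis, arbitrary units) of marker genes of motor neurons and other cell types over the 9 arrays, with lines from the lowest to the highest array. Slc18a3 lies at 13.4, Isl1 at 8.83 and Mbp at 10700, values of different probe sets that are not comparable amounts.

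Sex was not given in the labels and was uneven between groups by its transcripts. Xist, the RNA that silences an X chromosome in females, read 23.5 to 47.6 on the wild-type arrays and SMA 3, where the Y-linked translation factor Eif2s3y read 49 to 108.9. On SMA 1, SMA 2, transplanted SMA 1 and transplanted SMA 2, Xist read 600.7 to 879.5 and Eif2s3y 0.1 to 0.5. Transplanted SMA 3 had both, with Xist at 366.1 and Eif2s3y at 84.8. Several transcripts of skeletal muscle were highest on SMA 1 and SMA 2, where skeletal actin Acta1 read 1288.7 and 1413.7 against at most 27.1 elsewhere, and fast troponin C (Tnnc2) 299.6 and 586.2 against at most 11.9, but Tpm2 read highest on transplanted SMA 1 (127.3) and Car3 read 201.1 on wild type 3. These muscle genes were chosen after their values were seen.

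**Figure D2:**
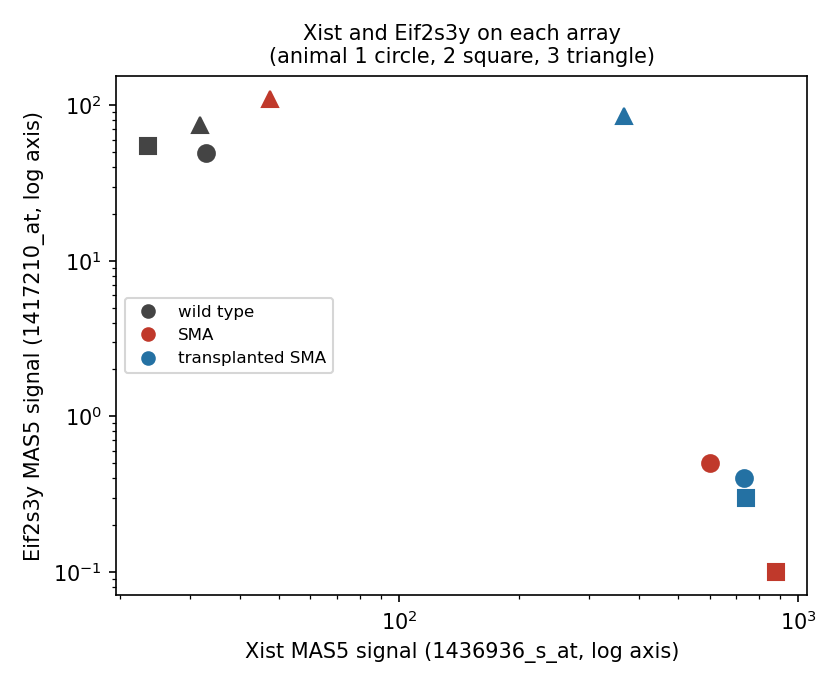
Xist against Eif2s3y signal (both axes log, MAS5 units), 1 point per array. Arrays with Xist at 600.7 or more have Eif2s3y at 0.5 or less, except that transplanted SMA 3 holds both at 366.1 and 84.8.

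The first comparison, SMA minus wild type, asks what the disease genotype changed in these cells. Hspb1, a small heat shock protein that neurons raise after injury, rose from 16.6 ± 4.6 to 173 ± 4.68 (SD, n = 3 each; log2 difference 2.54, SE 0.25, limma adjusted p = 0.00345), and its other probe set rose by 1.87 (SE 0.22, adjusted p = 0.0135). Sult1a1, a sulfotransferase of phenols, rose from 29.1 ± 7.29 to 151 ± 22.9 (1.89, SE 0.18, adjusted p = 0.00345). Mt2, a metallothionein that binds zinc and copper, rose from 854 ± 59.3 to 3170 ± 824 (1.84, SE 0.22, adjusted p = 0.0135). Cdkn1a, the p53-driven inhibitor of the cell cycle, rose from 16 ± 2.33 to 114 ± 39 (1.98, SE 0.28, adjusted p = 0.0464), and its brighter probe set, at 1.89 (SE 0.32), missed the threshold with an adjusted p of 0.135. The Cdkn1a call was lost with a pseudocount of 64, without a filter on dim probe sets, with only the 6 arrays compared, and without any one of wild type 1, 2 and 3, SMA 1, SMA 2, transplanted SMA 2 and transplanted SMA 3. Mt2 lost its call without any one of wild type 1, 2 and 3 and SMA 1, as did 1 of the Hspb1 probe sets without wild type 1, wild type 2 or SMA 1.

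These 5 probe sets of 4 genes were all that passed among 11313, and all were higher in each SMA animal than in any wild-type animal. At an unadjusted p under 0.05 there were 683 probe sets (307 higher and 376 lower in SMA, and 202 higher and 556 lower with median centring), where chance would give 566. That count was 437 without wild type 1, 487 without wild type 2 and 1123 with array weights. The 566 is only an average, because many probe sets can move together and counts can then lie far from it. Regrouping the same wild-type and SMA arrays in other ways gave 203 to 1459. The count of 683 is therefore not read as an excess, nor 437 as a deficit. The same caution applies to 566 in the later comparisons. Groups did not overlap for 1287 probe sets, 11.4% against 10% by chance. The count of 5 fell to 2 without wild type 1, without wild type 2 or without SMA 1, and to 3 without wild type 3. It was 9 without SMA 2 and 13 without SMA 3, the latter with Acta1, Atp2a1, Ckm and Mylpf of muscle and with Xist (named after their values were seen). With Xist or the muscle transcripts of each array as a covariate, or without SMA 1 and SMA 2, it was 0.

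**Figure D3:**
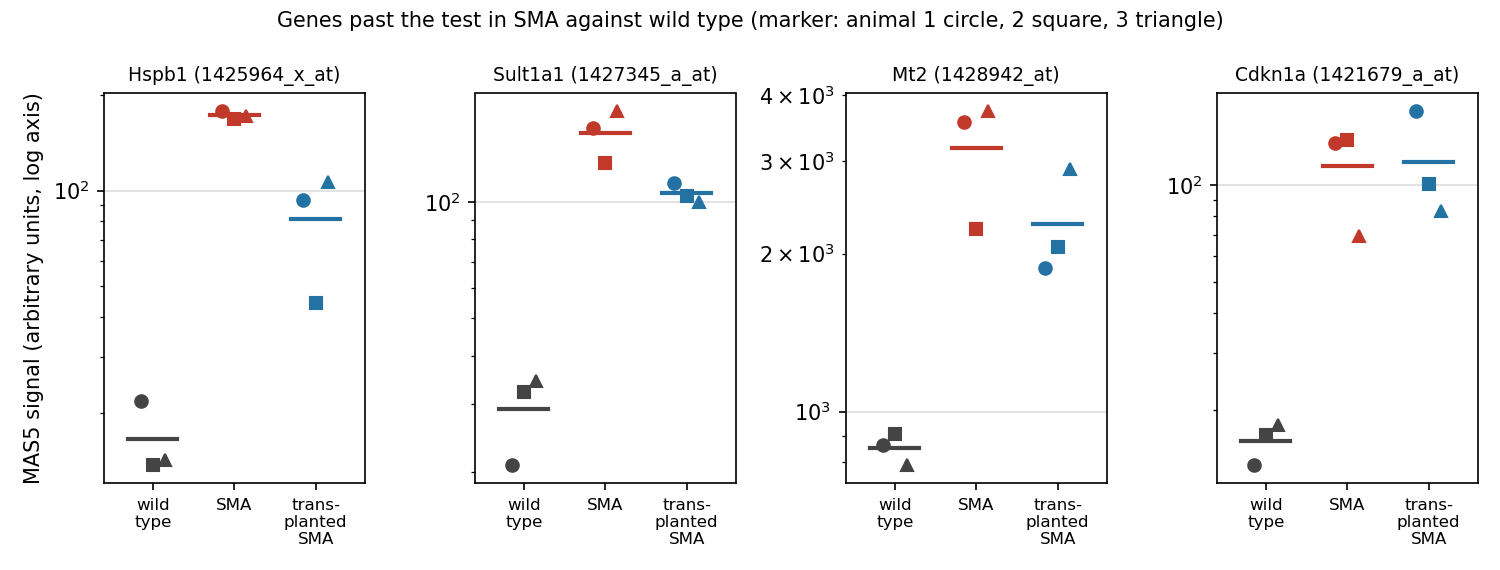
MAS5 signals (log axis) of the 4 genes past the threshold in SMA minus wild type, 1 probe set per gene, with 1 point per animal and a bar at each group's mean. The second called probe set of Hspb1 is not drawn. Hspb1 lies at 16.6 in wild type, 173 in SMA and 81.3 in transplanted SMA on average, and Cdkn1a at 16, 114 and 118.

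Genes next in order did not pass. Tsc22d3, a transcription regulator induced by glucocorticoids, differed by 1.18 (SE 0.2, adjusted p = 0.135), although its brightest probe set gave 0.47 and another 0.39. Values of -1.60 (SE 0.26) for Rsad2, an antiviral enzyme, and -1.66 (SE 0.28) for the myelin gap junction gene Gjb1 had the same adjusted p of 0.135. Mkrn1 gave -1.42 (SE 0.24), -1.10 (SE 0.23) and -0.82 (SE 0.2) at 3 probe sets but -0.13 at its brightest and -0.10 at another, so its probe sets disagree. Fech, the last enzyme of heme synthesis, gave -1.09 (SE 0.22, adjusted p = 0.343) and the chromatin protein Cbx5 -0.99 (adjusted p = 0.375). Neurofilament genes did not pass either, with -0.45 (SE 0.28) for Nefl, -0.42 (SE 0.42) for Nefm and -0.50 (SE 0.4) for Nefh. Differences were -0.22 (SE 0.27) for the chaperone Hspa5 of the endoplasmic reticulum, 0.26 (SE 0.59) for Gfap of astrocytes and -0.01 (SE 0.17) for Mbp, also not past the threshold.

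Genes of cholesterol synthesis fell together in SMA. All 19 tested members had a negative difference (median -0.58, camera adjusted p = 4.05e-17; adjusted p = 0.177 with an estimated correlation). Adjusted over the list alone 12 fell, and over all genes 0. Farnesyl diphosphate synthase Fdps read 305 ± 46.2 in wild type and 173 ± 10.7 in SMA (-0.76, SE 0.17), the sterol carrier Stard4 gave -0.78 (SE 0.19) and squalene epoxidase Sqle -0.68 (SE 0.2). Genes of oligodendrocytes, which make much cholesterol for myelin, were lower as a list too, with 26 of 28 negative (median -0.40, camera adjusted p = 7.21e-05; adjusted p = 0.783 with an estimated correlation). Adjusted over the list alone 0 passed, and examples were Gamt at -0.68, Gatm at -0.47 and Car2 at -0.47. By array, the oligodendrocyte list lay at -0.74 on SMA 1, -0.50 on SMA 2 and 0.30 on SMA 3 relative to the wild-type mean. Without SMA 1 the oligodendrocyte median was -0.12 (adjusted p = 0.122), without SMA 2 -0.23 and without SMA 3 -0.64, and it turned to 0.24 without SMA 1 and SMA 2 and to 0.41 with Xist or 0.07 with muscle transcripts (adjusted p = 0.477) as a covariate. The cholesterol list lay at -0.51, -0.62 and -0.57 on the 3 SMA arrays.

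Ribosomal protein genes rose as a list in SMA, by a small amount. Of 42 tested, 39 were positive (median 0.16, camera adjusted p = 1.42e-07; adjusted p = 0.278 with an estimated correlation), and 2 passed adjusted over the list alone and 0 over all genes. Rps25 gave 0.95, Rps27 0.81 and Rpl41 0.77. Immediate early and injury response genes, which neurons switch on after activity or damage, were positive in 20 of 21 (median 0.37, camera adjusted p = 5.53e-06; adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone 1 passed and over all genes 0, and Gadd45g gave 0.87 (SE 0.2), Gadd45b 0.91 (SE 0.26) and the phosphatase Dusp1 0.90 (SE 0.31). Without wild type 3 the immediate early median was 0.59.

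The p53 targets were higher as a list, with 16 of 20 positive (median 0.12, camera adjusted p = 0.0242; adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone 1 passed and over all genes 0 by the probe sets used; Cdkn1a led with 1.89, Trp53inp1 followed with 0.71 (SE 0.21) and Polk with 0.39. The p53 median was 0.05 without wild type 3, 0.07 without SMA 2 and 0.21 without SMA 3, and the call was lost without SMA 2 (adjusted p = 0.087) and without SMA 3 (adjusted p = 0.0738), with Xist (0.182) or muscle transcripts (0.0655) as a covariate, without SMA 1 and SMA 2 (0.104) and without the arrays numbered 3 (0.0688). Microglial genes were higher in 21 of 28 (median 0.20, camera adjusted p = 0.0454; adjusted p = 0.881 with an estimated correlation) and 0 passed adjusted over the list alone, with Grn at 0.45, Fcgr3 at 0.70 and C1qb at 0.72. Without wild type 1 the microglial median was -0.12 (adjusted p = 0.315), without wild type 3 0.54 and without SMA 1 0.35, and the call was also lost without SMA 2 (0.193) or SMA 3 (0.279), without shared-probe sets (0.0684), with the mean of all probe sets per gene (0.0532), without a filter on dim probe sets (0.0871) and with hybridisation controls (0.209) or muscle transcripts (0.717) as a covariate, and it was lost with a pseudocount of 64 (0.051) and without SMA 1 and SMA 2 (0.0585). Interferon response and MHC class I genes were lower in 9 of 15 (median -0.17, camera adjusted p = 0.0454; adjusted p = 0.783 with an estimated correlation). Adjusted over the list alone 1 passed and over all genes 0, with Rsad2 at -1.60, H2-K1 at -1.26 and Igtp at -0.57. Without wild type 3 the interferon median was 0.03 (adjusted p = 0.772), without wild type 2 -0.32, without SMA 1 -0.26 and without SMA 3 -0.10. The call was lost without SMA 1 (0.125), SMA 3 (0.163) or transplanted SMA 3 (0.0506), and with array weights (0.519). It was also lost with the replicate number as a block, with the mean of all probe sets per gene (0.0532) and without shared-probe sets (0.302). Leaving out SMA 1 and SMA 2, or the arrays numbered 3 (0.92), lost it too.

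Lists closest to the disease did not pass in SMA minus wild type. Motor neuron markers had a median of 0.08 (adjusted p = 0.739), cytoskeleton and axonal transport genes 0.07 (0.837), and SMN complex genes 0.03 (0.739). In the last of these, Snrpa1 of the U2 particle gave 0.83 and passed adjusted over the list alone. Heat shock genes had a median of 0.01 (adjusted p = 0.783) with Hspb1 as the 1 member past the threshold. Endoplasmic reticulum stress genes had -0.05 (0.127), where the chaperone Calr at -0.69 (SE 0.15) passed adjusted over the list alone, and oxidative phosphorylation genes -0.08 (0.0549). Meningeal and fibroblast genes, with Igf2 at 1.57 (SE 0.57), had a median of 0.29 (adjusted p = 0.054). Astrocyte genes had 0.07 (adjusted p = 0.254), with Mt2 called over all genes, and Mt1 at 1.54 (SE 0.29) past the threshold only adjusted over the list alone, as was the receptor Gpr37l1 on the lower side at -1.05 (SE 0.24). The 4 tested erythroid genes had a median of -0.90, led by Alas2 of heme synthesis at -1.31 (SE 0.28) and Bpgm at -0.72, and 2 of them were lower adjusted over the list alone. Of the 27 lists, 7 passed with camera, 0 with an estimated correlation, and 2 with fry, which were cholesterol synthesis and p53 targets (adjusted p = 0.0439 each). Of 29 other settings, the camera call stood in 28 for cholesterol synthesis, 27 each for ribosomal and immediate early genes, 23 for oligodendrocyte, 22 for p53, and 17 each for microglial and interferon genes. Over these settings the medians ranged from -0.70 to -0.44 for cholesterol synthesis, 0.10 to 0.20 for ribosomal, 0.24 to 0.59 for immediate early, -0.64 to 0.41 for oligodendrocyte, 0.05 to 0.21 for p53, -0.12 to 0.54 for microglial and -0.63 to 0.08 for interferon genes.

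The next comparison, transplanted SMA minus SMA, asks what the transplant changed in the captured cells of SMA animals. No probe set passed with limma, where the smallest adjusted p was 0.933; 540 had an unadjusted p under 0.05 (262 higher and 278 lower, and 205 higher and 323 lower with median centring), where chance would give 566. That count was 336 without SMA 2, 1062 without SMA 3, 857 with array weights, 999 without the arrays numbered 3, and 974 with Xist or 303 with muscle transcripts as a covariate. Groups did not overlap for 1031 probe sets, 9.11% against 10% by chance. The genes raised in SMA gave -1.02 (SE 0.22) and -1.02 (SE 0.25) at both probe sets of Hspb1, -0.45 (SE 0.18) for Sult1a1, -0.47 (SE 0.22) for Mt2 and 0.03 (SE 0.28) for Cdkn1a, none past the threshold over all probe sets. Adjusted over its list alone, Hspb1 was the 1 lower member of the heat shock list. SMA minus wild type used the same SMA arrays. Genes and lists found high or low there therefore tend to move back here without any effect of the transplant. Without SMA 3, 4 probe sets passed, of Acta1, Ckm, Mylpf and Zdhhc14 (named after their values were seen), the first 3 being muscle transcripts. With Xist as a covariate 3 passed, again Acta1, Ckm and Mylpf.

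Other genes with the smallest p, all at an adjusted p of 0.933, were the immediate early factor Fos at 1.92 (SE 0.44; 331 ± 209 and 1280 ± 754), the cytokine signalling inhibitor Socs3 at 1.70 (SE 0.4), the laminin Lama5 at 1.36 (SE 0.31) and the astrocyte receptor Gpr37l1 at 1.14 (SE 0.24), the 1 higher member of the astrocyte list adjusted over that list alone. On the lower side were Npl at -1.14 (SE 0.25), Ccdc80 at -0.81, Rbmx at -0.74 and the microtubule protein Mapt at -0.66 (SE 0.17). Neurofilament values were 0.45 for Nefl, 0.85 for Nefm and 1.02 (SE 0.4) for Nefh. Gfap gave 0.38, Mbp 0.20 and Hspa5 -0.16.

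Microglial genes were lower in the transplanted animals, with 25 of 28 negative (median -0.71, camera adjusted p = 1.09e-08; adjusted p = 0.545 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Cx3cr1, the fractalkine receptor, read 1170 in SMA and 548 after transplantation (-1.13, SE 0.33), Fcgr3 gave -1.08 and Cd53 -1.04. Relative to the wild-type mean the microglial list lay at -0.67, -0.76 and 0.26 on the transplanted arrays, 0.04, 0.37 and 0.22 on the SMA arrays, and -0.65, 0.03 and 0.62 on the wild-type arrays.

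Cholesterol synthesis genes were higher than in SMA given vehicle, with 18 of 19 positive (median 0.34, camera adjusted p = 5.82e-07, or 0.545 with an estimated correlation). Adjusted over the list alone or over all genes 0 passed. This list and the oligodendrocyte list were low on the same SMA arrays in SMA minus wild type. A rise here would therefore tend to appear without any effect of the transplant. Stard4 gave 0.63, Fdps 0.50 and Mvd 0.74. Oligodendrocyte genes were higher in 24 of 28 (median 0.21, camera adjusted p = 0.002; adjusted p = 0.552 with an estimated correlation) with 0 past adjusted over the list alone, Pllp at 0.94 and Gamt at 0.71. The oligodendrocyte call was lost without SMA 1 (adjusted p = 0.576), SMA 2 (0.114) or transplanted SMA 3 (0.534), with medians of 0.07, 0.13 and 0.07. The median was 0.47 without SMA 3 and 0.37 without transplanted SMA 1 or transplanted SMA 2, and it turned to -0.42 without SMA 1 and SMA 2 and to -0.12 with muscle transcripts as a covariate (adjusted p = 0.211).

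Immediate early genes were higher in 17 of 21 (median 0.56, camera adjusted p = 5.82e-07; adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone 6 rose and over all genes 0, with Fos and Socs3 as above and Dusp1 at 1.26 (SE 0.31). The immediate early median was 0.28 without SMA 1 (adjusted p = 0.00124) and 0.30 without transplanted SMA 1 (0.00242). Endothelial genes were higher in 23 of 26 (median 0.41, camera adjusted p = 0.000476; adjusted p = 0.552 with an estimated correlation), with Vtn at 0.80, Eng at 0.66 and Kdr at 0.63, and meningeal genes in 25 of 27 (median 0.38, camera adjusted p = 0.002; adjusted p = 0.552 with an estimated correlation), with Lum at 0.85 and Col6a1 at 0.80. In both lists 0 passed adjusted over the list alone. The endothelial call was lost without SMA 1 (adjusted p = 0.598, median 0.13) or transplanted SMA 1 (0.198, median 0.15), its median turning to -0.37 without SMA 1 and SMA 2 and reaching 0.85 without SMA 3, and it was lost with a stricter filter on dim probe sets (0.0581) and with muscle transcripts as a covariate (0.676, median -0.04). The meningeal call was lost without SMA 1 (0.391, median 0.15) or transplanted SMA 1 (0.422, median -0.16) and without SMA 1 and SMA 2 (0.995), and its median was 0.70 without transplanted SMA 3.

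Interferon response genes were higher in 13 of 15 (median 0.33, camera adjusted p = 0.002; adjusted p = 0.545 with an estimated correlation), with Lgals3bp at 0.85 and Igtp at 0.53, a call lost without transplanted SMA 1 (0.324, median 0.05) and with array weights (0.0509), with medians of 0.20 without SMA 3 and 0.50 without transplanted SMA 3. Glycolysis genes were higher in 14 of 16 (median 0.20, camera adjusted p = 0.011; adjusted p = 0.545 with an estimated correlation), with Pkm at 0.62 and Pfkm at 0.51, lost without SMA 2 (0.114, median 0.12) or transplanted SMA 2 (0.413, median 0.11), without SMA 1 and SMA 2 (0.334) and with muscle transcripts as a covariate (0.175). Ribosomal protein genes were lower in 34 of 42 (median -0.11, camera adjusted p = 0.002; adjusted p = 0.545 with an estimated correlation), with Rpl41 at -0.41 but Rpl37 at 0.34, lost without transplanted SMA 2 (0.07) and without the arrays numbered 3 (0.0966), and at -0.17 without transplanted SMA 1. Splicing factors were lower in 34 of 50 (median -0.08, camera adjusted p = 0.00932; adjusted p = 0.545 with an estimated correlation), with Rbm39 at -0.61, Rbm5 at -0.50 and Sf3b1 at -0.41, lost without SMA 2 (0.211, median -0.05) or transplanted SMA 3 (0.0863), without SMA 1 and SMA 2 (0.108), without the arrays numbered 3 (0.119), with a stricter filter on dim probe sets (0.0609) and with muscle transcripts as a covariate (0.0627), and at -0.14 without SMA 1 and -0.13 without transplanted SMA 2. In these 4 lists 0 members passed adjusted over the list alone or over all genes. Motor neuron markers had a median of 0.20 (adjusted p = 0.132), with Isl2 at 0.72 and Ache at 0.67, and SMN complex genes -0.10 (0.132). Neural stem and progenitor genes had a median of -0.02 (adjusted p = 0.492), with Id4 at -0.84. Of 27 lists, 10 passed with camera, 0 with an estimated correlation and 0 with fry. Of the 29 other settings, the camera call stood in 27 for microglial (medians -1.05 to -0.48), cholesterol (0.23 to 0.37) and immediate early genes (0.19 to 0.86), and in 25 for interferon (0.05 to 0.50) and ribosomal genes (-0.17 to -0.09). It stood in 24 for meningeal (-0.16 to 0.80), 23 for glycolysis (0.11 to 0.28), 22 for oligodendrocyte (-0.42 to 0.47) and endothelial (-0.37 to 1.01), and 21 for splicing genes (-0.14 to -0.05).

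The last comparison, transplanted SMA minus wild type, asks what remained different after transplantation. No probe set passed with limma (smallest adjusted p = 0.0805); 741 had an unadjusted p under 0.05 (370 higher and 371 lower, and 219 higher and 618 lower with median centring), and 1600 did not overlap, 14.1% against 10% by chance. The 741 became 503 without wild type 2, 512 without transplanted SMA 1 and 519 without wild type 1, 1221 with array weights and 1384 with Xist as a covariate, where chance would give 566. At a threshold of 0.10 there were 5. Dusp1 read 101 ± 19.8 in wild type and 519 ± 166 after transplantation (SD, n = 3 each; log2 difference 2.16, SE 0.31). Cdkn1a differed by 2.01 (SE 0.28), the chemokine Ccl3 by 1.54 (SE 0.23), Sult1a1 by 1.44 (SE 0.18) and Fech by -1.45 (SE 0.22), all at a limma adjusted p of 0.0805. Mt2 gave 1.37 (SE 0.22) and Bmpr2, a receptor of bone morphogenetic proteins, -1.68 (SE 0.27), both at 0.105. Further values not past the threshold were -1.55 for Isg20, -0.89 for Zfp638 and -1.28 for Mkrn1. The count of 0 was 7 without SMA 3 and 1 without transplanted SMA 2; it was 8 when only the 6 arrays compared were fitted, with array weights or without SMA 1 and SMA 2, and 9 with muscle transcripts as a covariate. Xist was among the calls in each of these fits except the one without transplanted SMA 2, where the 1 call was Hspb1. All wild-type arrays were Xist-low, so these added calls include a difference of sex. Nefl gave 0.00 (SE 0.28), Nefm 0.44, Nefh 0.51, Hspa5 -0.38, Gfap 0.64 and Mbp 0.19.

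By the medians of the main setting, immediate early genes stood highest above wild type after transplantation, though on transplanted SMA 1 the meningeal list lay higher. All 21 were positive (median 0.97, camera adjusted p = 1.28e-18; adjusted p = 0.226 with an estimated correlation), and 13 rose adjusted over the list alone, 0 over all genes. The median was 0.31 without a filter on dim probe sets, 0.62 with a pseudocount of 64 and 1.40 without the arrays numbered 3. Fos gave 2.19 (SE 0.44), Egr1 1.52 (SE 0.31) and Dusp1 2.16. By array the list lay at 1.44, 0.79 and 0.61 on the transplanted arrays and at 0.28, 0.52 and 0.40 on the SMA arrays, relative to the wild-type mean. Meningeal genes were positive in 25 of 27 (median 0.75, camera adjusted p = 3.13e-07; adjusted p = 0.747 with an estimated correlation), with Col6a1 at 1.05 and Vim at 0.91, and endothelial genes in 25 of 26 (median 0.43, camera adjusted p = 2.3e-05; adjusted p = 0.774 with an estimated correlation), with Ctla2a at 1.08 and Cldn5 at 0.86. In both, 0 passed adjusted over the list alone. The meningeal list lay at 1.73 on transplanted SMA 1, 0.23 on transplanted SMA 2 and 0.14 on transplanted SMA 3; without transplanted SMA 1 its median was 0.17 and that of the endothelial list 0.21 (adjusted p = 0.0922 each), and the endothelial call was also lost without wild type 2 (0.0907, median 0.25). Without wild type 3 the medians were 1.14 for meningeal and 0.68 for endothelial genes, and the meningeal one was 1.13 without transplanted SMA 3.

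Cholesterol synthesis genes were lower than in wild type in 15 of 19 (median -0.26, camera adjusted p = 0.000851; adjusted p = 0.747 with an estimated correlation), with 0 past adjusted over the list alone, Idi1 at -0.47, Fdft1 at -0.46 and Cyp51 at -0.45. The call was lost without wild type 2 (adjusted p = 0.0907), without transplanted SMA 1 (0.0555) and with Xist as a covariate (0.803), and the median was -0.13 without transplanted SMA 2. Microglial genes were lower in 22 of 28 (median -0.40, camera adjusted p = 0.000903; adjusted p = 0.774 with an estimated correlation), with 0 past adjusted over the list alone, Cx3cr1 at -0.98 and P2ry12 at -0.97. The call was lost without wild type 3 (0.894, median -0.11), transplanted SMA 1 (0.0922, median -0.23) or transplanted SMA 2 (0.239, median -0.24), and with Xist as a covariate (0.876), while the median was -0.76 without wild type 1 and -0.85 without transplanted SMA 3. Astrocyte genes were higher in 22 of 31 (median 0.12, camera adjusted p = 0.0147; adjusted p = 0.774 with an estimated correlation), and 2 rose adjusted over the list alone and 0 over all genes. Mt2 and Mt1 led that list at 1.37 and 1.12, and Slc1a2, the main glutamate transporter, gave 0.86. The astrocyte call was lost without wild type 2 (0.315), wild type 3 (0.135, median 0.06) or transplanted SMA 3 (0.67, median 0.01), without a filter on dim probe sets (0.233), without shared-probe sets (0.122) and without the arrays numbered 3 (0.823), and its median was 0.25 without wild type 1 and 0.22 without transplanted SMA 1. Motor neuron markers had a median of 0.27 (adjusted p = 0.095), with Isl2 at 0.83, and SMN complex genes -0.12 (0.402). Interferon genes had a median of 0.08 and a mean of -0.034, with camera's direction up (adjusted p = 0.754), and oligodendrocyte genes a median of -0.12 and a mean of 0 (0.471). The 4 erythroid genes had a median of -1.16, with Alas2 at -1.38 and Hbb-b2 at -1.35, and 1 passed adjusted over the list alone. Of 27 lists, 6 passed with camera, 0 with an estimated correlation and 0 with fry. Of the 29 other settings, the camera call stood in 27 for immediate early (medians 0.31 to 1.40), 26 for meningeal (0.17 to 1.47), 25 for endothelial (0.21 to 1.32), 24 for cholesterol (-0.48 to -0.13), 23 for microglial (-0.85 to -0.03) and 21 for astrocyte genes (-0.04 to 0.52).

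**Figure D4:**
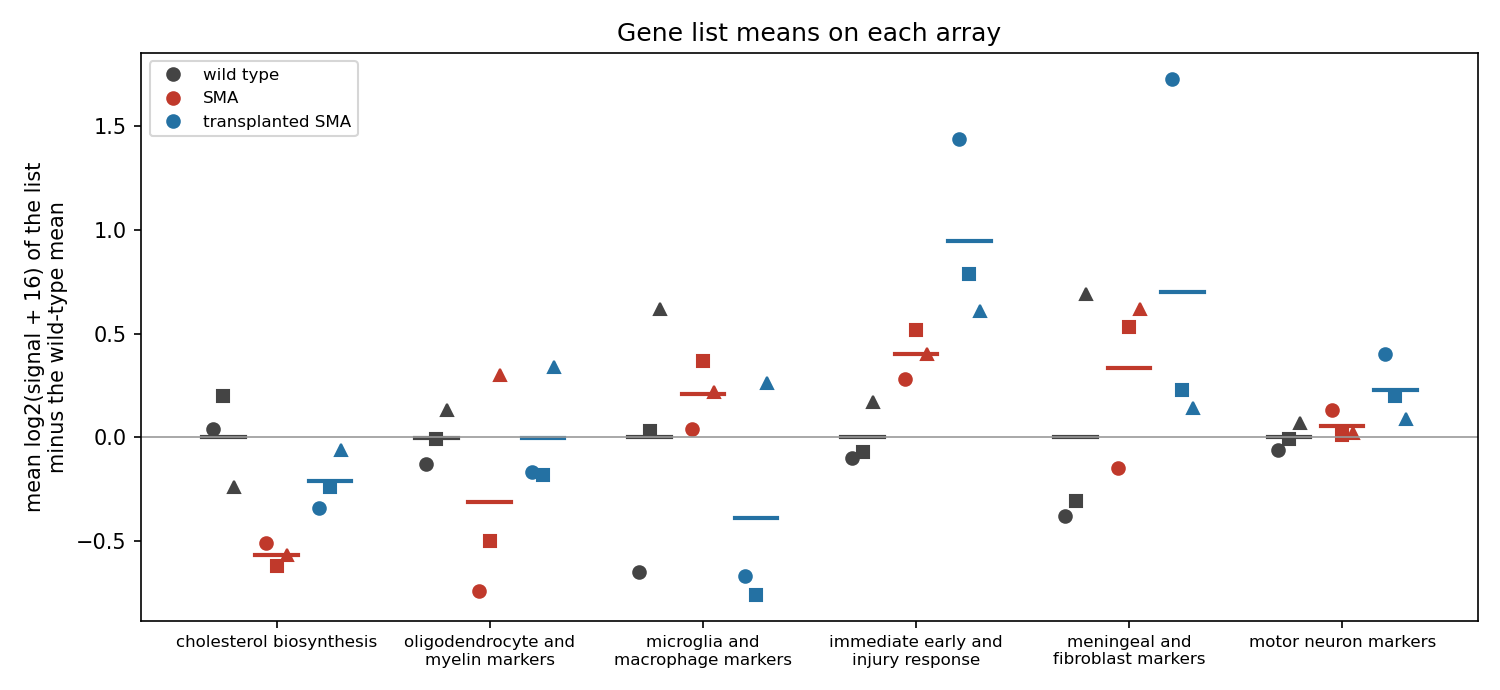
Mean log2(signal + 16) of 6 gene lists per array minus the wild-type mean (vertical axis), by group, where circles, squares and triangles mark animals 1, 2 and 3. Cholesterol genes lie at -0.51, -0.62 and -0.57 in SMA, and immediate early genes at 1.44, 0.79 and 0.61 after transplantation.

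Whether transplantation moved expression back towards wild type was asked over all tested probe sets. The covariance of SMA minus wild type with transplanted SMA minus SMA was -0.033, and unchanged groups sharing the SMA arrays gave -0.038 in 1000 simulations (95% interval -0.1 to 0.011). The covariance of SMA minus wild type with transplanted SMA minus wild type was 0.048, against 0.038 simulated for shared wild-type arrays (-0.01 to 0.1). The first became -0.08 without SMA 3 and -0.055 without SMA 1 (simulated -0.12 to -0.00022 in both), and the second 0.079 without wild type 3 (simulated 0.0018 to 0.14). The corresponding correlations across probe sets were -0.42 and 0.55, against -0.47 and 0.48 simulated. The simulations took the arrays of different groups as unrelated. Both covariances lay inside what shared arrays give without an effect. That 0 probe sets passed in both of the first comparisons follows from the 0 calls in transplanted SMA minus SMA, and so does not bear on this question.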

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

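The tests on other cell types in the SMA captures and the 3 tests on transplanted SMA 3 were chosen after the values they use were seen, and the Xist and muscle covariates after the data were examined; the splits of the arrays were planned.

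Transplanted SMA 3 held Xist at 366.1 and Eif2s3y at 84.8, a signal of both sexes on an array said to hold 1 animal. A swapped label is argued against as the whole cause, since Xist lay 10.8 times above the mean of the arrays that lack it while Eif2s3y was also present, and exchanging whole arrays does not bring both onto 1 array. RNA of a male and a female in equal parts cannot be told apart from other mixtures: Xist was at 47.2% of the Xist-high arrays, but Eif2s3y was at 118% (SD 37.8) and Kdm5d at 65.1% (SD 20.4) of the Xist-low arrays. Stem cells of the transplant in the capture also stay open, although the neural stem and progenitor list was lower there than on the highest other array (-0.39), because that list is bright (median member at percentile 86.5) and a small share would be hidden. The sex of the donor cells is not given in the sources used here.

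Hspb1, Sult1a1, Mt2 and Cdkn1a rose in SMA, and sex and muscle RNA moved with the same arrays. More RNA of another cell type cannot be told apart from the genotype: the highest median of 8 cell type lists was 0.29 (meningeal, SD 0.54), but several lists are bright (the median meningeal member at percentile 80.6 of all probe sets), where a small share would be hidden, and muscle is not among them. With Xist as a covariate 0 of the 5 probe sets passed, yet their differences went from 2.54 (SE 0.25) to 2.65 (SE 0.39) for Hspb1, from 1.87 (SE 0.22) to 1.64 (SE 0.34) for its other probe set, from 1.89 (SE 0.18) to 2.10 (SE 0.27) for Sult1a1, from 1.84 (SE 0.22) to 2.31 (SE 0.28) for Mt2, and from 1.98 (SE 0.28) to 1.25 (SE 0.32) for Cdkn1a; the errors widened for Hspb1 and Sult1a1, the difference fell for Cdkn1a and the 1.87 probe set, and Mt2 kept a small unadjusted limma p of 7.86e-06 that no longer passed the adjustment over all probe sets (adjusted p = 0.0754). With muscle transcripts as a covariate 0 passed as well, with 2.5 (SE 0.35), 1.59 (SE 0.28), 2.04 (SE 0.25), 2.12 (SE 0.28) and 1.52 (SE 0.32) in the same order of probe sets. Sex and muscle RNA therefore cannot be told apart from the genotype for these calls. SMA 3, which is Xist-low and has Acta1 at 1.5, still lay above every wild-type array for all 5 probe sets. The probe sets were called with SMA 3 in the test, so their selection favoured its place above wild type. The genotype stays open as the biological explanation.

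Cholesterol synthesis genes were lower in SMA in 19 of 19. Less oligodendrocyte RNA in the SMA captures is argued against as the whole cause, since with the oligodendrocyte list of each array as a covariate the median was -0.57 (SD of members 0.24, camera adjusted p = 4.54e-11) against -0.58 without. With Xist as a covariate the median was -0.47 (SD 0.39, camera adjusted p = 0.000215 at the preset correlation), with 18 of 19 still negative. That fit cannot separate sex from the genotype, because all wild-type arrays were Xist-low and SMA 3 was the only Xist-low SMA array. The median SE rose from 0.21 to 0.3. On SMA 3 the list lay at -0.57 relative to the wild-type mean, against -0.24 to 0.2 on the wild-type arrays. Sex is therefore not needed for the value of SMA 3, but it stays open for the other SMA arrays. Over all settings tried, the median ranged from -0.70 to -0.44 and the call was lost only with an estimated correlation. A response of lipid synthesis to the SMA genotype may be a candidate explanation, found and tested on the same 6 animals.

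Other splits of the 6 arrays of each comparison number 10 with the real one, too few for a share under 0.05. In SMA minus wild type the real split called 5 probe sets and the highest other 0, so 1 of the 10 reached the real count, and it gave 7 lists past the test against 10 at most, with 5 splits reaching the real count. In transplanted SMA minus SMA the real split called 0 and the highest other 4, so all 10 reached it, and it gave 10 lists against 13, with 4 splits reaching it. In transplanted SMA minus wild type the values were 0 and 0 (10 splits), and 6 lists against 11 (9 splits). Other splits reached the real number of lists in each comparison, so these numbers do not tell the real groups from other groupings. At an unadjusted p under 0.05, the real split gave 683 probe sets and the others 203 to 1459 in SMA minus wild type. In transplanted SMA minus SMA these counts were 540 and 302 to 1400, and in transplanted SMA minus wild type 741 and 190 to 698.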

How the results depend on the processing

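Fits with a covariate, without SMA 1 and SMA 2, or without the 3 arrays numbered 3 were chosen after seeing the data; all others were planned. Of 4435 values of named genes under the alternatives, 4326 kept direction and side of the threshold, 32 lost and 39 gained a call, 38 changed sign without a call and 0 reversed. Only the 5 probe sets called in SMA minus wild type had a call to lose, so the 32 losses were theirs. Most other values kept their side because the gene was never called, which says little about how firm the calls are. For gene lists past their test, 550 of 667 values stayed, 106 lost the call, 7 changed sign without a call and 4 reversed. Quantile normalisation and median centring moved the median of all probe sets by -0.08 at most. Where no reason is given, the cause was not tested. The 5 calls of SMA minus wild type became 2 with a stricter filter on dim probe sets, which tested only 2 of the 5. They became 0 with Xist or muscle transcripts as a covariate (smallest adjusted p 0.0754 and 0.0891) and 0 without SMA 1 and SMA 2 (0.063), which leaves 1 SMA array assumed to vary like the others. Without the 3 arrays numbered 3 there were 14 (12 higher and 2 lower), among them Acta1, Ckm, Mylpf and Xist, and leaving out each array in turn gave 2 to 13. With hybridisation controls as a covariate, all 5 calls and the cholesterol list (adjusted p = 7.06e-16) were kept. Transplanted SMA minus SMA had 0 calls, but 3 with Xist as a covariate, 6 without the arrays numbered 3 and 0 to 4 with each array left out. Transplanted SMA minus wild type had 0, but 2 with a pseudocount of 1, 8 with array weights, 8 with only the 6 arrays compared, 5 at a threshold of 0.10, 3 with hybridisation controls and 9 with muscle transcripts as a covariate, 8 without SMA 1 and SMA 2, 4 without the arrays numbered 3, and 0 to 7 with each array left out. In that comparison, the genes named among the calls without the arrays numbered 3 were Cdkn1a and Xist. Lists past the test in SMA minus wild type went from 7 to 11 with Xist as a covariate, 0 with an estimated correlation and 2 with fry. In transplanted SMA minus SMA they went from 10 to 0 with an estimated correlation and 0 with fry. In transplanted SMA minus wild type they went from 6 to 10 without the arrays numbered 3, 0 with an estimated correlation, 0 with fry, and 2 to 8 with each array left out. Oligodendrocyte genes in SMA minus wild type reversed to 0.41 with Xist as a covariate and 0.24 without SMA 1 and SMA 2; without these arrays transplanted SMA minus SMA reversed to -0.42 for oligodendrocyte and -0.37 for endothelial genes. Both covariances kept their sign with each array left out (-0.08 to -0.029, and 0.041 to 0.079). The sample numbers paired the arrays at most in part. Deviations of same-numbered arrays correlated at -0.083 to 0.45, with 6 of 9 pairs over 0.1. In 6 of 9 cases an array correlated best with its own number, so not every sample did and a partial pairing stays open. The arrays numbered 3 did go together, at 0.45, 0.27 and 0.14, with the highest hybridisation controls of each group, which the simulated covariances leave out. With the replicate number as a block the calls were 5, 0 and 0, and interferon genes in SMA minus wild type lost their call (adjusted p = 0.077). Signal over background limits what was tested: 20 of 32 motor neuron genes and Smn1 were too dim.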

Other observations

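The tests of the 3 lists below (glucocorticoid response, blood and muscle) were thought of after the comparisons were seen, and each left out the genes that raised the idea. Of the genes tested, Glul (astrocyte list), Slc4a1 (erythroid list) and the muscle gene Pvalb (interneuron list) were also in a list of the comparisons.

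Several groups of neuronal genes had small medians between the groups, although single arrays lay apart. Relative to the wild-type mean, the interneuron list lay at 0.37 on SMA 1 and -0.28 on SMA 3, and at 0.60 on transplanted SMA 2 and -0.34 on transplanted SMA 3. Synaptic vesicle genes had medians of -0.15 in SMA minus wild type (camera adjusted p = 0.254), 0.12 in transplanted SMA minus SMA (0.29) and -0.03 in transplanted SMA minus wild type (0.96), with Syngr1 at 0.53 and Sypl at -0.67 in the first. Ion channel and receptor genes had medians of 0.01, 0.13 and 0.09 in the same order (adjusted p = 0.739, 0.29 and 0.314), with the potassium channels Kcna1 at 1.66 (SE 0.51) and Kcnk1 at 0.84 (SE 0.24) in transplanted SMA minus wild type. Interneuron genes had 0.06, 0.09 and 0.12 (adjusted p = 0.739, 0.412 and 0.398). Neurotrophic factors and receptors had 0.04, 0.09 and 0.11 (adjusted p = 0.732, 0.302 and 0.221), where Igfbp3, a carrier of insulin-like growth factors, gave 1.28 (SE 0.32) in SMA minus wild type. None of these 4 lists passed in any comparison, and 0 of their members passed adjusted over the list alone.

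Housekeeping and glial precursor groups did not pass either. Proteasome and ubiquitin genes had medians of -0.10, 0.04 and -0.01 (adjusted p = 0.0998, 0.209 and 0.785), and lysosome and autophagy genes 0.08, -0.06 and 0.01 (0.315, 0.29 and 0.989). Cell cycle genes had -0.04, -0.04 and -0.11 (0.315, 0.943 and 0.418) and oligodendrocyte precursor genes 0.08, -0.12 and 0.04 (0.492, 0.412 and 0.989). Glycolysis genes had -0.08 in SMA minus wild type (0.202). Median and mean differed in sign for lysosome genes (0.01 and -0.005) and oligodendrocyte precursor genes (0.04 and -0.065) in transplanted SMA minus wild type, for cell cycle genes in transplanted SMA minus SMA (-0.04 and 0.009), for endothelial genes in SMA minus wild type (-0.02 and 0.08), and for cytoskeleton genes in transplanted SMA minus wild type (-0.02 and 0.012). Neural stem and progenitor genes had 0.00 in SMA minus wild type (adjusted p = 0.254), with Id4 at 0.96 (SE 0.26), and 0.10 in transplanted SMA minus wild type (0.627).

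A glucocorticoid response may accompany the genes raised in SMA, as a hypothesis. It came from Tsc22d3, Mt1, Mt2, Sult1a1 and Cdkn1a, several of which steroid hormones induce, and was tested on 15 other genes known to respond to them. Their median difference in SMA minus wild type was 0.54 (SD 0.5), at percentile 100 of 10000 random lists matched on mean signal. The random lists take genes as unrelated, although genes under 1 control move together. The hypothesis was found and tested on the same animals, so the percentile does not test it independently. Of these 15, 14 were positive and 4 passed adjusted over the list alone, and camera with an estimated correlation gave p = 0.000967, not adjusted over lists. Fkbp5, which dampens the hormone's receptor, gave 1.05 (SE 0.27), Hif3a 1 (SE 0.23), the clock gene Per1 0.86 (SE 0.28) and Ddit4 0.85 (SE 0.25), whereas Gpd1 gave -0.79 (SE 0.32); over all genes none of these passed. By array the median lay at 0.36, 0.56 and 0.76 above the wild-type mean on SMA 1, SMA 2 and SMA 3, and at 0.13, 0.17 and 0.31 on the transplanted arrays. Each wild-type array was set against the mean of the other wild-type arrays only, and lay between -0.14 and 0.10. SMA 3 is Xist-low like the wild-type arrays and without raised muscle transcripts (Acta1 at 1.5), so neither sex nor muscle RNA is needed for its value. In each group, however, the array numbered 3 had both the highest median of this list and the highest hybridisation controls. Whether such array differences raise the list was not tested. Hypoxia or other stress also induces some of these genes, which was not tested.

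Less blood in the SMA tissue could lower Alas2, Fech, Bpgm and Rsad2, but the test did not decide. Another 16 reticulocyte and heme synthesis genes had a median of -0.07 (SD 0.34) in SMA minus wild type, at percentile 8.47 of 10000 matched random lists, with 12 of 16 negative, 0 past adjusted over the list alone and p = 0.574 in camera with an estimated correlation. By array the median lay at -0.33, 0.43 and -0.43 on the SMA arrays, so the animals of the group went both ways. Slc25a37, the mitochondrial iron importer, gave -0.77 (SE 0.25), and Hba-a1 was too dim to test.

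Skeletal muscle RNA in the captures of SMA 1 and SMA 2 is a candidate source of the Acta1, Ckm and Mylpf calls made without SMA 3. On SMA 1 and SMA 2, 33 other muscle genes had medians of 0.73 and 0.91 above the wild-type mean, both at percentile 100 of 10000 matched random lists, with 8 and 16 of 33 more than 1 log2 unit higher against at most 3 on any other array. Wild type 3 also had 28 of 33 above the mean of the other wild-type arrays, as did SMA 1, but with a median of 0.23 (percentile 89.3). On SMA 3 the median was 0.02 (percentile 24.3), and on the other arrays the percentiles were 2.97 to 89.3. Myl1 read 150.3 and 189 on SMA 1 and SMA 2 and at most 10.8 elsewhere. How muscle RNA would reach neurons cut by laser was not tested.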
